A study of Mus musculus with 63 samples.

How the data were processed

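The deposited table of expected counts, which per the submitters' processing notes came from RSEM 1.3.0 with Bowtie 1.2.2 on mm10 after bcl2fastq 2.20.0.422, gave the values used here. Per the labels' protocols, islets were isolated on a Histopaque gradient, mCherry-positive cells were sorted, RNA was taken with TRIzol or a Qiagen column, and libraries were made with Takara SMART-Seq v4 and Nextera XT, which keep no strand. The table held 20306 genes in 63 libraries, of which 48.5% of values were not whole, and they were rounded to counts. The authors' normalized signal values are, as deposited, expected counts divided by a factor per library. That table held 16455 genes (3851 of mean expected count at or below 1 were left out) and was used only for its factors, which match a median of ratios within 0.017%. Symbols were matched for 19344 genes by name and 887 by synonym, and 75 kept the deposited name. Replicate numbers here only follow the order of the labels. Y-linked genes fitted the labelled sex (lowest male sum 34.8 CPM, highest female sum 1.29 CPM over 48 libraries with a label).

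Genes were kept with filterByExpr by group in edgeR 4.0.16 (R 4.3.3) and scaled with TMM. A single quasi-likelihood fit (glmQLFit with robust priors, glmQLFTest, two-sided) held 9 group means and a term for RNA extraction over all 63 libraries. Benjamini-Hochberg adjustment ran over 16092 genes in each of 10 comparisons, and calls were taken at 0.05. Fold errors were taken from the F statistic, and log2 CPM used a prior count of 1. Gene positions are those of GRCm38.p6, the assembly also called mm10.

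The 28 gene lists, fixed before the data were examined, were β cell transcription factors, hormone and granule genes, glucose sensing and excitability, maturity markers, disallowed genes, progenitor and dedifferentiation genes, proliferation, chaperones of the endoplasmic reticulum, integrated stress response, interferon, MHC class I, NF-kB and cytokines, oxidative phosphorylation, glycolysis, cholesterol synthesis, hypoxia, ChREBP and glucose response, dissociation response, and markers of alpha, delta and PP, acinar, duct, endothelial, stromal, myeloid, lymphoid, Schwann and erythroid cells. All 529 list genes were found. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists of a comparison. The 2 gene sets of maturation were also tested with fry, a rotation test of whether the set's own genes differ that does not compare them with other genes. Members were counted with p adjusted over all genes and again over the list alone.

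The maturation score is the mean z over genes rising at least 2-fold from E18.5 to Adult minus that over genes falling, z taken from the mean and SD of the ICR adults after the extraction effect was removed with removeBatchEffect, the groups kept. The step left 31 falling genes with no count in any adult out of the score, a choice made after the data were seen. The spread of a group is each library's mean of 1 minus the Pearson correlation with the others over the 2000 genes of highest mean. Both were compared with exact permutation tests, and the difference between models with 100000 random permutations. For the spread, the libraries' distances were permuted between the groups and not computed anew for each regrouping.

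The genes named are, for Adult vs E18.5, T1D vs T1ND and T2D vs T2H, the 6 largest rises and 6 largest falls among called genes of at least 10 CPM in the higher group with every library of the smaller group on the same side of the other group's median. Other group comparisons took 3 and 3, and the difference of effects 4 and 4 without the condition on libraries. Symbols starting with Gm and a number, mt-, Igh, Igk, Igl, AC or AL, ending in Rik or holding -ps, and sex-linked marker genes were left out. Up to 4 called members of smallest adjusted p stand for each list (2 of smallest p where none was called), beside 18 anchor genes such as *Ins1*, *Ucn3* and *Mafa*. Some genes that this rule picks are not reported here.

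Alternatives fixed before the data were examined were DESeq2 1.42.0, voom with sample weights, median-ratio (RLE) factors, no low-count filter, at least 5 CPM in 3 libraries, no extraction term, Qiagen or TRIzol libraries alone, a term for libraries whose labels carry an S number above 60, only the compared groups, at least 2-fold, terms for sex and age, 1 copy of Ins2-Cre alone, estimated correlation, and each of the 63 libraries left out. Added after the data were seen were terms for the acinar, stromal and myeloid lists, fits without the 4 libraries above 1% stroma or the 7 above 20% acinar share, fits without 159 genes that follow the acinar list across the ICR adults (Spearman above 0.8), the authors' factors, the score with genes of no adult counts, single libraries left out of shares and of the difference in spread, fits without T2D 1 and T2H 1, and the score without T2H animals above 84 days or with log2 age as a term in a linear model.

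The method was first run on simulated counts with 200 changed genes per comparison, 100 of each size. It found 69% of 2-fold and 92% of 4-fold changes in Adult vs E18.5, 45% and 88% in P1 vs E18.5, 29% and 84% in P7 vs P1, 43% and 91% in P10 vs P7, 77% and 97% in Adult vs P10, 86% and 96% in T1ND vs Adult, 56% and 94% in T1D vs T1ND, 90% and 96% in T2H vs Adult, 71% and 95% in T2D vs T2H, and 34% and 89% in the difference of effects. Unchanged genes called were 1 to 12 per comparison, and of 100 null sets 0 to 2 were called. The simulation holds no RNA of other cells and no outlying library. It draws each gene independently of the others, so its null sets cannot test the preset correlation of 0.01 used for the lists.

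For genes with few counts, a group at 0 is given as a bound against a floor of 3 counts, and one at 1 to 3 counts as a ratio with a 95% counting interval. Raw reads, single-cell data and measurements other than these expected counts were not used here.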

Results

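The data are RNA sequencing of 63 libraries of sorted mouse β cells in 9 groups. ICR mice gave cells shortly before birth (E18.5, n = 4), at postnatal days 1 (P1, n = 3), 7 (P7, n = 3) and 10 (P10, n = 5), and as adults of 84 to 364 days (Adult, n = 21). NOD-ICR mice were non-diabetic (T1ND, n = 7, blood glucose 108 to 245 mg/dl) or diabetic (T1D, n = 4, 311 to 358 mg/dl and 1 animal above the limit of 600). Non-diabetic ob/+ mice (T2H, n = 9, 103 to 271 mg/dl) were of strain BTBR, and diabetic ob/ob mice (T2D, n = 7, 408 to 534 mg/dl and 5 animals above 600) were labelled BTBR/mix. Libraries held 23894167 to 73839270 expected counts (median 36444826), and 16092 of 20306 genes were tested. A gene is called changed below where its adjusted p (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg over all tested genes) lies below 0.05. Folds are log2 values ± standard error, CPM values are means ± SD, and gene lists were fixed beforehand and tested with camera at a preset correlation of 0.01.

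RNA of other cell types was measured in each group with marker lists. Acinar genes, which code for digestive enzymes, held 0.135 ± 0.123% of counts at E18.5, 9.94 ± 8.10% at P7, 0.297 ± 0.251% at P10, 8.99 ± 8.72% in ICR adults, 14.8 ± 6.80% in T1ND, 23.3 ± 11.7% in T1D, 11.3 ± 14.1% in T2H and 8.53 ± 13.8% in T2D. Single libraries carry some of these means: without E18.5 4 it was 0.0747%, without P7 3 6.35% and without T2D 3 3.43%. Stromal genes, mostly collagens and mural cell genes, held 1.52 ± 1.40% at P1 and 1.59 ± 1.45% at P7, and at most 0.0442% in any E18.5 library (0.837% without P1 3 and 0.92% without P7 1). Myeloid genes, which mark macrophages and their kin, held 0.242 ± 0.193% in T1ND, 0.554 ± 0.311% in T1D and 0.133 ± 0.095% in T2D, against 0.0177% in ICR adults. The insulin genes *Ins1* and *Ins2* together held 36.9% of counts in ICR adults, 32.4% in T1ND, 25.5% in T1D, 36.8% in T2H and 31.8% in T2D. All shares are parts of the same library total, so the insulin shares are not free of the acinar shares.

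**Figure D1:**
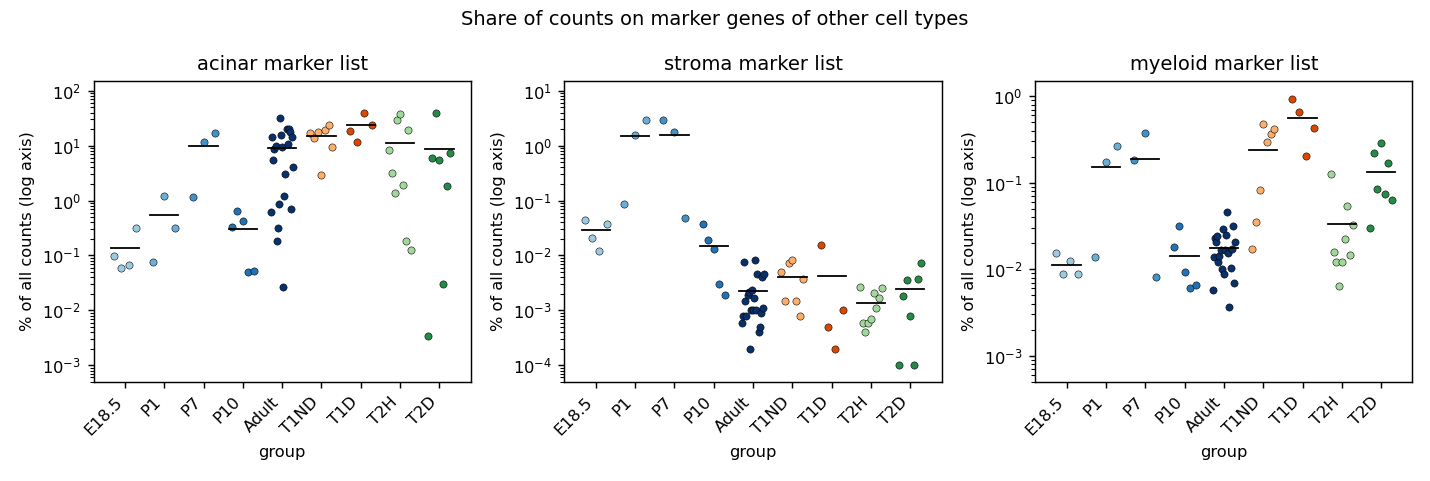
Percentage of all expected counts of a library that fell on the acinar, stromal and myeloid marker lists, on log axes. Each point is a library, and each bar is the group mean, such as 23.3% for acinar genes in T1D.

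Which genes separate adult from fetal β cells? Between E18.5 (n = 4) and Adult (n = 21), *Ucn3*, a peptide hormone and late marker of β cell maturity, rose by 3.21 ± 0.41 (78.1 ± 4.53 to 760 ± 150 CPM). *Dlk1*, an imprinted growth regulator of fetal tissues, fell by 8.93 ± 0.43 (523 to 1.05 CPM, adjusted p = 3.39e-24, edgeR), and *Nnat*, an imprinted gene of young β cells, fell by 6.92 ± 0.33. The largest rises and falls by the fixed rule also held *Syt10*, a calcium sensor of vesicle fusion (7.26 ± 0.89), *Gad2*, an enzyme that makes GABA (7.17 ± 1.03), and *Pdyn*, an opioid peptide precursor (6.86 ± 0.87). Among the falls were *Igfbpl1* (-8.27 ± 0.77), *Mycl*, a gene of the Myc family (-7.67 ± 0.87), *Igf2bp3*, a fetal RNA-binding protein (-6.78 ± 0.50), and *Mfng*, which modifies Notch receptors (-6.40 ± 0.54). In all, 5594 genes changed, 2507 higher and 3087 lower in adults, and 3147 of them by at least 2-fold.

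By list, 25 of 28 proliferation genes fell and 1 rose (26 and 1 adjusted over the list alone, list adjusted p = 4.06e-23, camera), with *Mki67*, an antigen of cycling cells, at -3.71 ± 0.48 and *Ccna2*, a cyclin, at -3.37 ± 0.30. Of 21 progenitor and dedifferentiation genes, 11 fell and 3 rose (12 and 3 over the list alone, adjusted p = 8.43e-08), among them *Fev*, a transcription factor of endocrine progenitors, at -4.63. Among the 3 that rose was *Aldh1a3*, an enzyme of retinoic acid synthesis, at 4.67 ± 1.44. Of 16 maturity markers 7 rose and 2 fell (8 and 2 over the list alone, adjusted p = 0.00261, and adjusted p = 0.537 with an estimated correlation), with *Syt4*, a synaptotagmin that tunes insulin release, at 3.64 ± 0.32 and *Prlr*, the prolactin receptor, at 2.34 ± 0.26. *Mafa*, a transcription factor of mature β cells, stood at 1.15 ± 0.50 (adjusted p = 0.0642, edgeR) and was not called. Of 22 genes that β cells keep silent (disallowed genes) 10 fell and 1 rose (12 and 1 over the list alone, adjusted p = 0.000414, and 0.537 as adjusted p with an estimated correlation), including *Ldha*, a lactate dehydrogenase subunit, at -2.11 ± 0.55 and *Slc16a1*, a carrier of lactate and pyruvate, at -1.68 ± 0.67.

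Of 44 oxidative phosphorylation genes 30 fell and 2 rose (33 and 2 over the list alone, adjusted p = 5.04e-08, and adjusted p = 0.537 with an estimated correlation), such as *Atp5b*, a subunit of ATP synthase, at -0.93. Of 24 integrated stress response genes 8 rose and 1 fell (8 and 1 over the list alone, adjusted p = 0.0427, and adjusted p = 0.718 with an estimated correlation), such as *Trib3*, a stress-induced pseudokinase, at 2.59. *Ins1* (0.24, adjusted p = 0.577, edgeR) and *Ins2* (0.55, adjusted p = 0.217) were not called. Beside these groups, 17 of 20 acinar genes rose (18 over the list alone), among them the digestive enzymes *Ctrc* (7.17 ± 1.88), *Pnlip* (6.99 ± 1.86) and *Ctrl* (6.75 ± 1.86). Of 14 stromal genes 10 fell (10 over the list alone), with the collagen *Col1a2* at -3.97. Duct genes held 0.221 ± 0.0187% of counts at E18.5 and 0.0979 ± 0.0234% in adults. Of 20 dissociation response genes, which respond to handling of cells, 10 fell and 3 rose (12 and 3 over the list alone, adjusted p = 0.00823, and adjusted p = 0.718 with an estimated correlation). Among libraries of the same extraction method 3231 (TRIzol) and 1861 (Qiagen column) genes changed, the latter with 1 E18.5 library.

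What changes across birth? From E18.5 (n = 4) to P1 (n = 3), 15 of 24 chaperones of the endoplasmic reticulum fell and none rose (23 lower over the list alone, adjusted p = 4.59e-16, camera, and adjusted p = 0.0879 with an estimated correlation), including *Hsp90b1* at -1.09 ± 0.24. Of 23 hormone and granule genes 9 fell (16 over the list alone, adjusted p = 1.11e-11, and adjusted p = 0.0931 with an estimated correlation), such as *Slc30a8*, the zinc transporter of insulin granules, at -1.35. *Prlr* fell by 1.91 ± 0.31, *Nkx6-1*, a β cell transcription factor, by 1.16, and *Ins1* fell as well (adjusted p = 0.0474, edgeR). Of 22 disallowed genes 12 rose (15 over the list alone, adjusted p = 4.56e-09, and adjusted p = 0.105 with an estimated correlation), with *Ldha* at 3.44 ± 0.87 and *Igfbp4*, a binding protein of insulin-like growth factors, at 4.55 ± 0.77.

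Along with these groups, 11 of 14 stromal genes rose (13 over the list alone), such as *Col1a2* at 5.66 ± 1.47, and 13 of 20 myeloid genes rose (17 over the list alone), such as *Lyz2*, lysozyme of macrophages, at 5.62. The NF-kB and cytokine list had 13 of 20 members higher and 2 lower (17 and 2 over the list alone, adjusted p = 7.74e-05, and adjusted p = 0.136 with an estimated correlation), with the chemokine *Cxcl1* at 7.07. Of 20 dissociation response genes 8 rose (15 over the list alone, adjusted p = 1.91e-09, and adjusted p = 0.105 with an estimated correlation). Endothelial genes rose in 2 of 13 members (6 over the list alone, adjusted p = 0.000259, and adjusted p = 0.291 with an estimated correlation) and lymphoid genes in 5 of 19 (7 over the list alone, adjusted p = 0.022, and adjusted p = 0.388 with an estimated correlation). The largest rises were *Tpsab1*, a mast cell tryptase (9.80 ± 1.69), *Lrrn4*, a gene of mesothelium (8.84 ± 1.68), and *Fap*, a fibroblast protease (8.05 ± 1.82). The largest falls were *Srbd1* (-2.32), *Cotl1* (-2.02) and *Prlr*. In all 1938 genes changed, 1388 higher and 550 lower (71.6% higher, and 81.1% higher with median-ratio size factors, which put the median fold of all genes at 0.129 against 0.041). Without the 4 P1 and P7 libraries above 1% stroma, which leaves 1 P1 library, 26 genes were called, and with a stroma term 131. Leaving out single libraries gave 299 (P1 3), 950 (P1 2), 3281 (P1 1), 954 (E18.5 2) and 864 (E18.5 3). With a myeloid term 101 genes were called, with voom 6356 and among Qiagen libraries, with 1 library in each group, 0.

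What changes in the first postnatal week? From P1 (n = 3) to P7 (n = 3), 17 genes changed, 9 higher and 8 lower (717 with an unadjusted p below 0.05, edgeR). *Prlr* rose by 1.51 ± 0.32 (adjusted p = 0.0286) and *Gls2*, a glutaminase, by 4.29 ± 0.83. *Nnat* fell by 2.72 ± 0.60, *C2cd4a*, a nuclear factor linked to β cell function, by 2.43 ± 0.41 (40.6 to 7.49 CPM), *Gp9*, a platelet glycoprotein, by 3.64 ± 0.72, and *Elovl6*, a fatty acid elongase, by 1.17 ± 0.26. *Akr1c6*, a steroid dehydrogenase of liver, rose by 7.73 ± 1.66. *Clec4f*, a lectin of liver macrophages, had 1 count over the 3 P1 libraries and was 8150 times higher at P7, with a counting interval of 1460 to 322000 (such intervals cover counting error only). Which cells the RNA of these liver genes came from was not tested.

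No member of 20 glycolysis genes was called over all genes and 6 were lower over the list alone (adjusted p = 3.97e-13, camera, and 0.000514 with an estimated correlation), such as *Tpi1*, triose phosphate isomerase, at -0.75 (adjusted p = 0.0533, edgeR). Of 21 progenitor genes 1 fell (1 over the list alone, adjusted p = 4.68e-05, camera, and 0.0023 with an estimated correlation). All 20 acinar genes lay higher at P7 with a median of 3.25, none called in the gene test (adjusted p = 5.82e-15 as a list, and adjusted p = 0.192 with an estimated correlation). The dissociation response list had a median of -0.595, none called (adjusted p = 5.97e-05, and adjusted p = 0.342 with an estimated correlation). Duct genes (median -0.51), lymphoid genes (0.881) and endothelial genes (1.06) moved as lists as well, none called (adjusted p = 0.000429, 0.00262 and 0.0237, and 0.192, 0.268 and 0.673 with an estimated correlation). Other tools and subsets gave 0 (only these groups fitted) to 536 (voom) genes.

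What changes from day 7 to day 10? From P7 (n = 3) to P10 (n = 5), 13 of 16 maturity markers rose (14 over the list alone, adjusted p = 2.37e-10, camera, and 0.0289 with an estimated correlation). *Ucn3* rose by 1.56 ± 0.45 (177 to 508 CPM), *Syt4* by 1.82, *Slc2a2*, the glucose transporter of β cells, by 1.26, *Trpm5*, a cation channel, by 1.66, and *Ins1* by 1.39. Of 23 hormone and granule genes 20 rose (20 over the list alone, adjusted p = 9.63e-13, and 0.0473 with an estimated correlation), such as *Rab3a*, a small GTPase of vesicles, at 1.23 and *Snap25*, a vesicle fusion protein, at 1.15. Of 23 glucose sensing genes 13 rose (14 higher and 1 lower over the list alone, adjusted p = 2.05e-07, and 0.0473 with an estimated correlation), among them *Glp1r*, the incretin receptor, at 2.60 ± 0.86. Of 20 β cell transcription factors 12 rose (15 over the list alone, adjusted p = 2.99e-09, and adjusted p = 0.0548 with an estimated correlation), with *Neurod1* at 1.16, *Insm1* at 1.53 and *Pax6* at 1.02.

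The disallowed list fell in 21 of 22 members (21 over the list alone, adjusted p = 9.63e-13, camera, and 0.0473 with an estimated correlation), with *Ldha* at -5.00 ± 0.85, *Slc16a1* at -4.65 and *Igfbp4* at -5.22. Beside it, all 14 stromal genes fell (14 over the list alone), with *Lum*, a matrix proteoglycan, at -7.13 ± 1.32 and *Col1a2* at -6.77. Of 19 lymphoid genes 15 fell (16 over the list alone), of 20 acinar genes 11 (19 over the list alone), with *Ctrb1*, a digestive protease, at -4.76, of 20 myeloid genes 15 (17 over the list alone, adjusted p = 6.53e-06, and adjusted p = 0.279 with an estimated correlation), and of 10 delta and PP cell genes 5 (5 over the list alone, adjusted p = 0.013, and adjusted p = 0.265 with an estimated correlation). Of 20 dissociation response genes 15 fell (17 lower and 1 higher over the list alone, adjusted p = 4.92e-12, and adjusted p = 0.0606 with an estimated correlation), with *Klf6*, an immediate early factor, at -2.90. *Dlk1* fell by 2.42 and *Txnip*, a glucose-induced arrestin, by 2.04. *Mki67* stood at -0.58 (adjusted p = 0.547, edgeR). The largest falls were the liver plasma proteins *Ahsg* (-12.95 ± 1.91, 260 ± 411 to 0.0207 CPM) and *Kng1*, with 1 count over the 5 P10 libraries and a ratio of 19800 (3560 to 784000), and *Clec4f*, with 0 counts at P10 and at least 4410-fold lower (floor of 3 counts over the group). Which cells gave the RNA of these genes at P7 was not tested.

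Between these days 4731 genes changed, 1685 higher and 3046 lower (35.6% higher, and 23.5% higher with median-ratio size factors, which put the median fold of all genes at -0.194 against -0.037). Stromal genes held 0.0475 to 2.92% of counts in the P7 libraries, and 264 genes were called with a stroma term and 7 without the 4 libraries above 1% stroma, which leaves 1 P7 library. Without P7 1, 2 and 3 in turn the counts were 2779, 1585 and 6072. With only these groups fitted 1656 genes were called, with a myeloid term 1202, with voom 7803, among Qiagen libraries 358 and among TRIzol libraries, with 1 P7 library, 1728.

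What remains to change after day 10? Between P10 (n = 5) and Adult (n = 21), 25 of 28 proliferation genes fell and 1 rose (25 and 1 over the list alone, adjusted p = 3.57e-25, camera, and 0.0227 with an estimated correlation), with *Mki67* at -2.43 ± 0.43, *Ccna2* at -2.28 and *Aurka*, a mitotic kinase, at -1.64. *Nnat* fell by 3.12, *Dlk1* by 5.41 ± 0.40 and *Pyy*, a peptide hormone of young islets, by 3.44 ± 0.45 (1502 to 186 CPM). *Npy*, a neuropeptide of the same family, rose by 2.05 ± 0.61. Of 16 maturity markers 4 rose (4 over the list alone, adjusted p = 0.124), such as *Prlr* at 1.71 ± 0.22 and *Syt4* at 1.59, while *Ucn3* (0.53, adjusted p = 0.228, edgeR), *Ins1* (-0.38, adjusted p = 0.35) and *Ins2* (0.04, adjusted p = 0.95) were not called.

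Of 24 integrated stress response genes 10 rose (15 higher and 1 lower over the list alone, adjusted p = 1.92e-05, camera, and adjusted p = 0.198 with an estimated correlation), with *Trib3* at 2.02 and *Ddit3*, a stress transcription factor, at 1.24. Of 20 β cell transcription factors 6 fell (6 over the list alone, adjusted p = 0.124), such as *Mnx1* at -1.06 and *Pdx1* at -0.75. *Txnip* rose by 1.75. The largest rises were *Pnlip* (7.34 ± 1.70), *Sycn*, a zymogen granule protein (6.45), and *Tmem59l* (6.34 ± 0.49, 0.587 to 45.9 CPM), and the largest falls *Msln*, a surface protein of mesothelium (-7.04 ± 0.59), *Eln*, elastin (-5.82), and *Dlk1*. Beside them, 16 of 20 acinar genes rose (19 over the list alone) and 7 of 14 stromal genes fell (9 over the list alone). In all 3029 genes changed, 1423 higher and 1606 lower, 1557 of them by at least 2-fold. Among Qiagen libraries 1003 were called, among TRIzol libraries 1195 and with voom 4850.

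How do β cells of non-diabetic NOD-ICR mice (n = 7) differ from those of ICR adults (n = 21)? All 35 interferon response genes rose (35 over the list alone, adjusted p = 4.57e-93, camera, and 1.21e-05 with an estimated correlation). *Igtp*, an interferon-induced GTPase, rose by 5.64 ± 0.27 (9.01 ± 2.26 to 445 ± 336 CPM). Of 19 genes of MHC class I presentation 18 rose (18 over the list alone, adjusted p = 4.97e-56, and 1.97e-05 with an estimated correlation), with *B2m*, the light chain of class I, at 5.24 ± 0.35 (31.2 to 1284 CPM) and *Psmb8*, an immunoproteasome subunit, at 3.55. NF-kB and cytokine genes rose in 12 of 20 members and fell in 1 (14 and 1 over the list alone, adjusted p = 2.09e-08, and 0.0488 with an estimated correlation), such as *Icam1*, an adhesion molecule, at 3.88. *Tgtp1* (8.90 ± 0.59) and *Tgtp2* (9.23 ± 0.54), interferon-induced GTPases whose reads cannot be told apart with certainty, and *Lefty1*, a secreted Nodal inhibitor (9.09 ± 0.69), were the largest rises. *Tmem14c* (-3.74) and *Iqcg* (-3.61) were among the largest falls.

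Beside these groups, 16 of 20 myeloid genes rose (17 over the list alone, adjusted p = 1.31e-16, camera, and adjusted p = 0.0568 with an estimated correlation), such as *H2-Eb1*, an MHC class II chain, at 5.26. Of 19 lymphoid genes 12 rose (14 over the list alone, adjusted p = 6.61e-07, and adjusted p = 0.0568 with an estimated correlation), such as the chemokine *Ccl5* at 6.81. Of 20 dissociation response genes 6 rose (7 over the list alone, adjusted p = 0.00068, and adjusted p = 0.37 with an estimated correlation). Delta and PP cell genes rose in 4 of 10 members (5 over the list alone, adjusted p = 0.00478, and adjusted p = 0.237 with an estimated correlation) and duct genes in 4 of 12 (5 over the list alone, adjusted p = 0.0251, and adjusted p = 0.37 with an estimated correlation). The acinar list had a median of 0.495, none called (adjusted p = 0.0419, and adjusted p = 0.754 with an estimated correlation). Of 22 disallowed genes 9 rose (13 over the list alone, adjusted p = 7.12e-07, and adjusted p = 0.182 with an estimated correlation), with *Ldha* at 1.304. *Dlk1* rose by 2.85, and *Pam*, an enzyme that amidates peptides, by 2.05 ± 0.31. *Trpm5* fell by 1.02, *Slc30a8* by 0.68 and *Aldh1a3* by 3.37 ± 0.95. *Ucn3* (-0.63, adjusted p = 0.1, edgeR), *Ins1* (0.01, adjusted p = 0.987) and *Ins2* (-0.18) were not called. In all 2231 genes changed, 1510 higher and 721 lower. Strain and autoimmune state differ together here, all 7 T1ND libraries were Qiagen column libraries, and 776 genes were called with a myeloid term.

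Which genes differ between diabetic (n = 4) and non-diabetic (n = 7) NOD-ICR β cells? *Ucn3* fell by 2.43 ± 0.40 (500 to 91.9 ± 53.8 CPM, adjusted p = 0.000803, edgeR) and *Frzb*, a secreted Wnt antagonist, by 2.49 ± 0.37 (112 ± 58.5 to 20.1 ± 3.14 CPM, adjusted p = 9.48e-05). *Txnip* rose by 1.77 ± 0.41 (103 ± 94.6 to 375 ± 140 CPM, adjusted p = 0.018), and its glucose-induced relative *Arrdc4* by 1.53 ± 0.38. The 6 largest rises also held *Fabp5*, a fatty acid carrier (1.84 ± 0.44), *Gsto2*, a glutathione transferase (1.66 ± 0.42), *Sat1*, the enzyme that acetylates polyamines (1.59 ± 0.30), and *Ifi30*, a lysosomal thiol reductase (1.32 ± 0.25). The 6 largest falls also held *Gipr*, the receptor of the incretin GIP (-2.05 ± 0.48), *Jph3*, which joins membranes of excitable cells (-1.99 ± 0.38), *Mpp3*, a scaffold protein (-1.87 ± 0.40), and *Mlxipl*, the glucose-responsive transcription factor ChREBP (-1.86 ± 0.46).

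In T1D, 4 of 23 glucose sensing and excitability genes fell (9 lower and 1 higher over the list alone, adjusted p = 1.33e-05, camera, and adjusted p = 0.339 with an estimated correlation): *Gipr*, *Trpm5* (-1.61 ± 0.36), *Gpd2*, the mitochondrial glycerol phosphate dehydrogenase (-0.95 ± 0.21), and *Pcx*, pyruvate carboxylase (-1.32 ± 0.37, adjusted p = 0.0499, edgeR). Of 20 β cell transcription factors 2 fell (5 over the list alone, adjusted p = 6.69e-06, camera, and adjusted p = 0.436 with an estimated correlation), *Mlxipl* and *Mnx1*, a homeobox factor that holds β cell identity (-1.43 ± 0.34). Of 16 maturity markers 2 fell, *Ucn3* and *Trpm5* (6 over the list alone, adjusted p = 0.0258, and adjusted p = 0.569 with an estimated correlation). *Mafa* (-1.45 ± 0.54, adjusted p = 0.151, edgeR), *Slc2a2* (-1.09 ± 0.32, adjusted p = 0.0684) and *Npy* (-2.41 ± 0.74, adjusted p = 0.0793) were not called. None of 23 hormone and granule genes was called (0 over the list alone, adjusted p = 0.926), and *Ins1* (0.16) and *Ins2* (0.06) stood near 0. *Aldh1a3* (0.49) and *Neurog3*, the factor that starts endocrine fate (-0.10), were not called, and 0 of 21 progenitor genes was called (1 lower over the list alone, adjusted p = 0.566).

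In T1D, 3 of 20 glycolysis genes fell (3 lower and 1 higher over the list alone, adjusted p = 0.926), the isozymes *Aldoc* (-1.35 ± 0.30) and *Eno2* (-1.16 ± 0.28) and the phosphofructokinase subunit *Pfkm* (-0.64). Of 44 oxidative phosphorylation genes 2 rose (9 over the list alone, adjusted p = 7.91e-12, and adjusted p = 0.436 with an estimated correlation), *Cox5a*, a subunit of cytochrome oxidase (0.73 ± 0.17), and *Uqcrfs1*, the iron-sulfur subunit of complex III (0.68 ± 0.18). No interferon (1 over the list alone), MHC class I, NF-kB, chaperone or proliferation gene was called, while the medians of these lists were 0.43, 0.58, 0.64, 0.38 and 0.50 (adjusted p = 3.88e-06, 7.04e-08, 0.0105, 9.28e-05 and 0.000103, camera). With an estimated correlation their adjusted p was 0.546, 0.339, 0.546, 0.547 and 0.547. Beside all these groups the acinar list had a median of 1.42 (adjusted p = 0.00059, and adjusted p = 0.737 with an estimated correlation) and the myeloid list one of 1.31 (1 higher over the list alone, adjusted p = 1.3e-07, and adjusted p = 0.447 with an estimated correlation), none called over all genes. The dissociation response list had a median of 0.47, none called (adjusted p = 0.0258, and adjusted p = 0.737 with an estimated correlation).

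In all 206 genes changed in T1D, 78 higher and 128 lower, 107 of them by at least 2-fold. With a myeloid term 12 of the 206 were still called, 206 kept their direction, and their folds were multiplied by a median of 0.862. Without the libraries above 20% acinar share (2 T1D and 1 T1ND in these groups) 6 genes were called, and with only these groups fitted 0. Leaving out single libraries gave 24 to 684 genes. Without an extraction term 79 were called, with an age term 124, among Qiagen libraries 0, with DESeq2 576.0 and with voom 1821. A stroma term gave 366, and the fit without the 4 libraries above 1% stroma 326.

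How do β cells of BTBR ob/+ mice (n = 9) differ from those of ICR adults (n = 21)? Of 24 integrated stress response genes 12 rose (17 over the list alone, adjusted p = 9.34e-21, camera, and 0.000289 with an estimated correlation). *Chac1*, an enzyme that degrades glutathione, rose by 1.83 ± 0.28, *Phgdh* and *Psat1*, enzymes of serine synthesis, by 1.70 and 1.32, and *Asns*, asparagine synthetase, by 1.18 ± 0.19 (111 to 215 CPM). Of 24 chaperones 6 rose and 1 fell (14 and 1 over the list alone, adjusted p = 2.62e-07, and adjusted p = 0.585 with an estimated correlation), such as *Herpud1*, a protein of degradation in the endoplasmic reticulum, at 1.03. Of 44 oxidative phosphorylation genes 6 rose (20 over the list alone, adjusted p = 1.47e-12, adjusted p = 0.29 without the extraction term, and adjusted p = 0.585 with an estimated correlation), such as *Sdhc*, of succinate dehydrogenase, at 0.47. Proliferation genes rose in 3 of 28 members (10 over the list alone, adjusted p = 2.04e-05, and adjusted p = 0.585 with an estimated correlation), such as *Cdc20*, a mitotic activator, at 1.29.

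The largest rises were *Dio1*, a thyroid hormone deiodinase (5.23 ± 0.48), *Mapk4* (2.71) and *Oxtr*, the oxytocin receptor (1.85), and the largest falls *Aox1*, aldehyde oxidase (-2.72 ± 0.47), *Pdlim4* (-1.69) and *Crocc*, of ciliary rootlets (-1.43). *Gipr* fell by 1.29, *Mnx1* by 0.81 and *Eno2* by 0.88. *Ucn3* (-0.27, adjusted p = 0.574, edgeR) and *Ins1* (0.73, adjusted p = 0.0517) were not called. The acinar list had a median of 2.29 with 0 of 20 called (adjusted p = 6.64e-05, camera, adjusted p = 0.29 without the extraction term, and adjusted p = 0.648 with an estimated correlation). Of 20 myeloid genes 1 rose (2 over the list alone, adjusted p = 0.000507, and adjusted p = 0.585 with an estimated correlation), at a mean share of 0.0331% (0.0212% without T2H 1) against 0.0177%. Of 12 duct genes 2 rose (4 over the list alone, adjusted p = 0.0318, adjusted p = 0.631 without the extraction term, and adjusted p = 0.585 with an estimated correlation). In all 836 genes changed, 64.8% of them higher and 294 lower. Strain and genotype differ together here, 8 of 9 T2H libraries but 4 of 21 ICR adults were TRIzol libraries, and 93 genes were called among TRIzol libraries and 17 among Qiagen libraries, the latter with 1 T2H library. With a sex term 303 were called, with an age term 319, without T2H 9 386, without Adult 13 551, with 1 copy of Ins2-Cre alone 1294 and with DESeq2 1279.

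Which genes differ between diabetic ob/ob (n = 7) and ob/+ (n = 9) β cells? *Ucn3* fell by 2.03 ± 0.31 (591 ± 166 to 149 ± 59.7 CPM, adjusted p = 2.11e-06, edgeR), *Slc2a2* by 2.198 ± 0.27 (333 ± 97 to 74.9 ± 29 CPM, adjusted p = 1.89e-08) and *Mafa* by 1.68 ± 0.44 (109 to 28.9 CPM, adjusted p = 0.00445). *Cck*, the gut hormone cholecystokinin, rose by 8.11 ± 1.05 (0.176 ± 0.169 to 57.2 ± 45 CPM, adjusted p = 7.3e-08), *Slc5a10*, a sugar transporter, by 6.35 ± 0.78 (1.35 ± 1.39 to 121 ± 64.9 CPM) and *Dlk1* by 5.03 ± 0.51 (0.923 ± 0.578 to 29.6 ± 21.7 CPM). The 6 largest rises also held *Tm4sf20*, a membrane protein (6.04 ± 1.14), *Sorcs2*, a sorting receptor (4.83 ± 0.83), and *Cartpt*, a neuropeptide precursor (4.83 ± 1.05). The 6 largest falls were *Syt10* (-6.64 ± 0.69, to 0.189 CPM in T2D), *Crhr1*, the receptor of corticotropin-releasing hormone (-5.85 ± 0.58), *Penk*, the enkephalin precursor (-5.58 ± 0.92), *Npy* (-5.32 ± 0.69, 186 ± 134 to 5.47 ± 4.62 CPM), *Slc39a8*, a metal ion importer (-4.32 ± 0.61), and *Rasl11b*, a small GTPase (-4.07 ± 0.57).

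Of 16 maturity markers 11 fell and none rose (12 lower and 1 higher over the list alone, adjusted p = 6.28e-10, camera, and 0.0306 with an estimated correlation), including *Trpm5* at -3.24 ± 0.31 and *Sytl4*, which docks insulin granules, at -1.93 ± 0.28. Of 23 glucose sensing genes 10 fell and 1 rose (11 and 1 over the list alone, adjusted p = 5.37e-06, and adjusted p = 0.0686 with an estimated correlation), among them *Kcnj11*, the pore of the ATP-sensitive potassium channel, at -1.52 ± 0.24. Of 20 β cell transcription factors 7 fell and 1 rose (7 and 1 over the list alone, adjusted p = 0.00416, and adjusted p = 0.468 with an estimated correlation), with *Nkx6-1* at -1.36 ± 0.22 and *Insm1* at -1.11, and *Rfx6*, a factor of islet development, higher at 1.15 ± 0.21. Hormone and granule genes were split, 4 higher and 7 lower of 23 (8 and 8 over the list alone, adjusted p = 0.448, median 0.12 and mean -0.08). *Ins1* fell by 1.02 ± 0.28 (117000 ± 50650 to 64350 ± 37010 CPM, adjusted p = 0.00566, edgeR), *Ins2* was not called (-0.36, adjusted p = 0.418), and *Slc30a8* fell by 1.45 ± 0.23. Of 21 progenitor genes 6 rose and 1 fell (6 and 1 over the list alone, adjusted p = 0.0838), the rises including *Cck*, *Slc5a10*, *Dlk1*, *Aldh1a3* (3.74 ± 0.89, 22.4 ± 46.7 to 206 ± 97.4 CPM) and *Gast*, the gastrin precursor (3.64 ± 0.78), while *Neurog3* (-0.42) was not called.

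Metabolic groups moved as follows. Of 16 ChREBP and glucose response genes 5 rose (7 over the list alone, adjusted p = 0.000282, camera, and 0.0306 with an estimated correlation), with *Arrdc4* at 2.44 ± 0.32, *Klf10*, a transcription factor, at 1.97 ± 0.21 and *Pklr*, a pyruvate kinase, at 1.28. *Txnip*, looked up here after its value in T1D was seen, rose by 1.54 ± 0.34. Of 22 cholesterol synthesis genes 10 rose (15 over the list alone, adjusted p = 2.36e-07, and adjusted p = 0.0686 with an estimated correlation), with *Fdft1*, squalene synthase, at 1.70 ± 0.18 and *Hmgcs1*, of the mevalonate pathway, at 0.96. Of 24 chaperones 9 rose (10 over the list alone, adjusted p = 0.000282, and adjusted p = 0.468 with an estimated correlation), such as *Derl1*, of protein export from the endoplasmic reticulum, at 0.82 ± 0.12 and *Hspa5*, its main chaperone, at 0.76. Of 20 glycolysis genes 4 rose and 1 fell (4 and 1 over the list alone, adjusted p = 0.0407, and adjusted p = 0.468 with an estimated correlation), with *Eno1* at 1.296 ± 0.16 and *Gpi1* at 1.08 ± 0.12. Of 20 hypoxia genes 7 rose and 4 fell (7 and 4 over the list alone, adjusted p = 0.131), with *Pfkfb3*, a regulator of glycolysis, at 4.33 ± 0.64 and *Slc2a1*, a widespread glucose transporter, at -1.30.

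Proliferation genes fell in 22 of 28 members (23 over the list alone, adjusted p = 2.6e-17, and adjusted p = 0.0626 with an estimated correlation), with *Top2a*, a topoisomerase of dividing cells, at -3.40 ± 0.51, *Nusap1*, of the mitotic spindle, at -3.64, *Mki67* at -2.66 ± 0.54 and *Birc5*, survivin, at -2.66. Beside these groups, 8 of 20 myeloid genes rose (13 over the list alone, adjusted p = 1.61e-05, camera, and adjusted p = 0.468 with an estimated correlation), such as *Cd68* at 2.22 and *Cx3cr1* at 2.40. The acinar list had a median of -2.06 (1 of 20 lower and 0 over the list alone, adjusted p = 0.00355, adjusted p = 0.0788 without the extraction term, and adjusted p = 0.773 with an estimated correlation), with the amylase *Amy2a5*, whose reads cannot be told from those of its copies, at -4.37. In all 2937 genes changed, 1569 higher and 1368 lower, 1406 of them by at least 2-fold. Among Qiagen libraries, with 1 T2H library, 25 genes were called, and with only these groups fitted 1293. The labelled strain (BTBR/mix in T2D and BTBR in T2H) differs together with genotype and diabetes here.

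**Figure D2:**
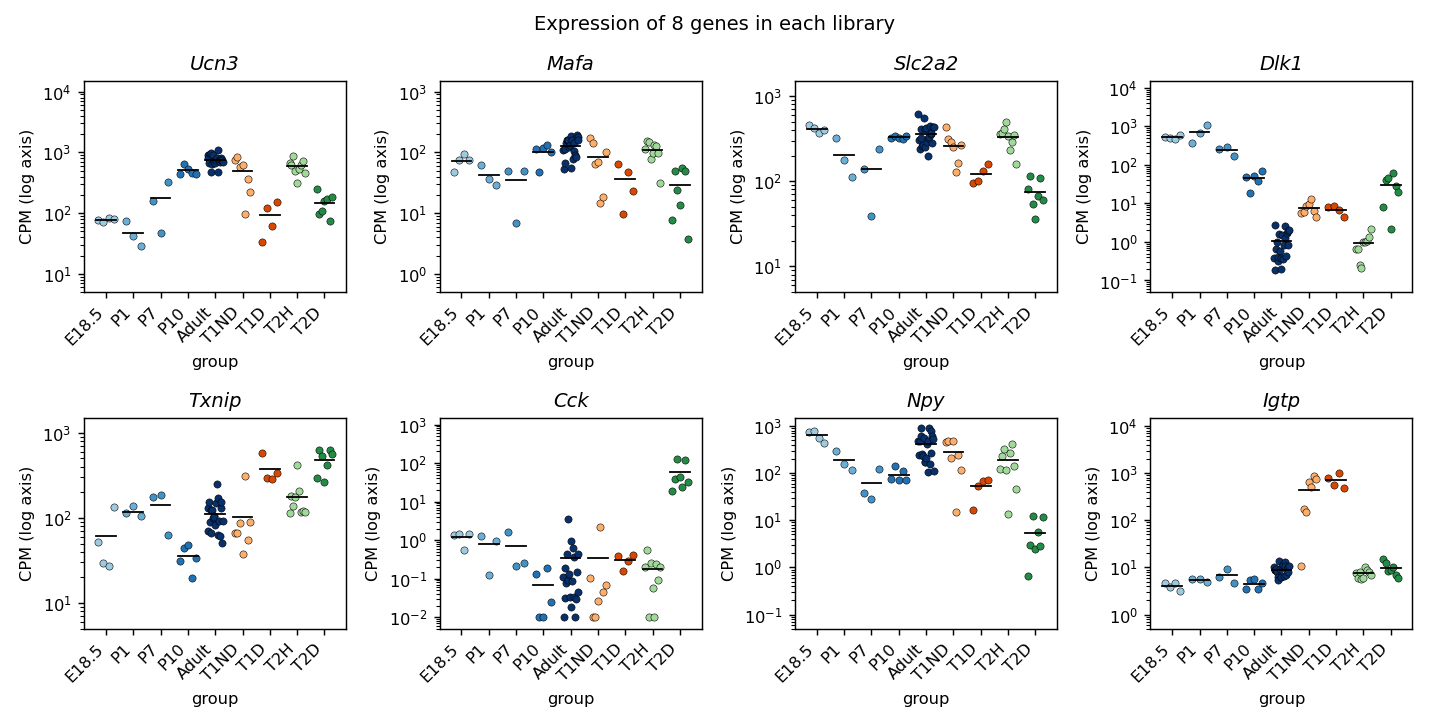
CPM of 8 genes in each library on log axes, with 1 point per library and a bar at the group mean, such as 760 CPM for *Ucn3* in ICR adults. Values below 0.01 CPM are drawn at 0.01.

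Do the diabetes models shift β cells along the path from fetal to adult? A score was built from the genes that changed at least 2-fold from E18.5 to Adult (1377 rising and 1739 falling scored), as the mean z of the rising genes minus that of the falling ones, each gene scaled by its own SD over the ICR adults. It was -6.52 ± 0.31 at E18.5, -6.66 ± 0.38 at P1, -5.28 ± 0.88 at P7 and -3.28 ± 0.14 at P10, with the ICR adults at 0 by construction (SD of the score 0.30). Stromal RNA moved with these steps. P7 3, with 0.0475% stroma, stood at -4.27, and P7 1 and P7 2, with 2.92% and 1.79%, at -5.83 and -5.75, through their falling genes (2.10 against 3.93 and 3.77). The falling genes stood at 3.97 in P1 and 3.09 at E18.5. T1ND stood at -0.807 ± 0.42 and T1D at -1.53 ± 0.22, a difference of -0.726 (exact permutation p = 0.0152, two-sided, 330 regroupings). T2H stood at -0.683 ± 0.25 and T2D at -1.14 ± 0.38, a difference of -0.457 (exact permutation p = 0.0083, two-sided, 11440 regroupings). Among the 4 T2D and 8 T2H TRIzol libraries it was -1.102 (exact permutation p = 0.00202), and among the Qiagen libraries, with 1 T2H library, -0.24. In each of these settings z was taken from the ICR adults of that method alone (4 TRIzol or 17 Qiagen). The scales therefore differ, and these sizes cannot be set against -0.457. T2D animals were 58 to 78 days old and T2H animals 53 to 179. Without the T2H animals above 84 days (4 left) the difference was -0.462 (exact permutation p = 0.0848), and with a term for log2 age over these groups alone -0.466 ± 0.18 (p = 0.0233, linear model). The same term gave -0.651 ± 0.24 in T1D (p = 0.0277). In T1D the rising genes gave -0.436 (exact permutation p = 0.0152) and the falling genes 0.29 (exact permutation p = 0.0636), and in T2D they gave -0.332 (exact permutation p = 0.00603) and 0.126 (exact permutation p = 0.378). With genes of the step from P10 to Adult the differences were -0.0953 in T1D (exact permutation p = 0.479) and -0.187 in T2D (exact permutation p = 0.158).

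**Figure D3:**
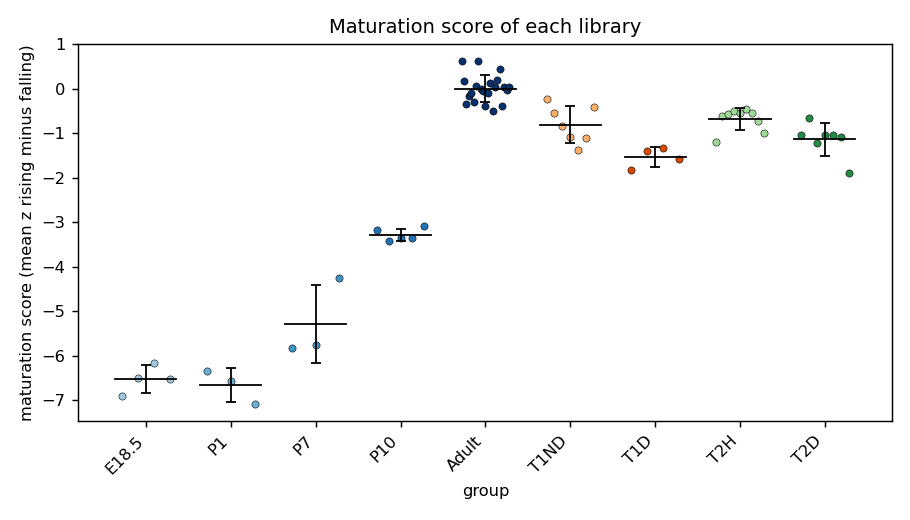
Maturation score of each library (mean z of rising genes minus that of falling genes), with the ICR adult mean at 0. Points are libraries, and lines with bars are group means ± SD, such as -1.53 ± 0.22 in T1D.

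As gene sets, the 1377 rising genes had 32 members lower and 2 higher in T1D (70 and 6 over the list alone, adjusted p = 0.000135, camera, and 0.046 with an estimated correlation). The 1770 falling genes had 11 higher and 5 lower (9 and 4 over the list alone, adjusted p = 0.00238, and adjusted p = 0.238 with an estimated correlation). In T2D 255 rising genes were lower and 98 higher (269 and 122 over the list alone, adjusted p = 0.00166, and adjusted p = 0.117 with an estimated correlation), and of the falling genes 193 were higher and 206 lower (12.1% and 12.7% of all over the list alone, adjusted p = 0.729). Of genes lower in T1D 50 had risen from E18.5 to Adult (19.9 expected from the totals alone), and of genes lower in T2D 387 (213 expected). Of genes higher in T1D 42 had fallen with age (15 expected), and of genes higher in T2D 386 (301 expected). Genes lower in T2D that had also fallen with age numbered 298 (262 expected), and genes higher in T2D that had risen 207 (244 expected). With the step from P10 to Adult all 4 overlaps of T2D exceeded expectation. Of its higher genes 180 had risen (139 expected) and 226 had fallen (157 expected). Of its lower genes 220 had risen (121 expected) and 215 had fallen (137 expected). In T1D 5 higher genes had risen (6.9 expected) and 21 had fallen (7.78 expected). Of the lower ones 15 had risen (11.3 expected) and 21 had fallen (12.8 expected).

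Do animals of a group differ more from each other in diabetes? The mean distance of a library to its group (1 minus the correlation over 2000 genes) was 0.0584 ± 0.0079 in T1D and 0.106 ± 0.0206 in T1ND, a difference of -0.0473 (exact permutation p = 0.00303, two-sided, the smallest possible). In T2D it was 0.241 ± 0.0823 and in T2H 0.182 ± 0.0717, a difference of 0.0594 (exact permutation p = 0.152). Without the 159 genes that follow the acinar list, the distance was 0.1115 in T2D and 0.09136 in T2H. The difference there was 0.02019 (exact permutation p = 0.149). In T1D and T1ND the distance was then 0.06606 and 0.1151, so T2H no longer lay above T1ND. The T2D and T2H distances thus rest in large part on genes that follow the acinar list. Each library's distance was computed within its real group and not again for each regrouping. Distances within a group share pairs and are not independent, so these p values are not valid as exact tests of spread. Without T2D replicate 1 the T2D difference over 2000 genes was -0.00914 (exact permutation p = 0.808).

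Where do the effects of the diabetes models differ? *Dlk1* differed by 5.17 ± 0.81 (T2D effect minus T1D effect, adjusted p = 6.11e-05, edgeR), *Cck* by 8.06 ± 1.69, *Sorcs2* by 5.93 ± 1.39 and *Slc5a10* by 5.52 ± 1.21. *Crhr1* differed by -5.82 ± 0.76 (adjusted p = 9.25e-07), *Ube2c*, a ubiquitin-conjugating enzyme of mitosis, by -4.77 ± 0.78, *Top2a* by -4.46 ± 0.73 and *Syt10* by -4.42 ± 0.90. *Rfx6* (2.02 ± 0.35) and *Mlxipl* (2.11) differed upward, and *Trpm5* (-1.62) and *G6pc2*, a glucose phosphatase of β cells (-1.22), downward. *Ucn3* (0.40 ± 0.47, adjusted p = 0.743), *Mafa* (-0.23 ± 0.68, adjusted p = 0.924), *Slc2a2* (-1.11, adjusted p = 0.145), *Npy* (-2.91, adjusted p = 0.0625) and *Aldh1a3* (3.25, adjusted p = 0.303) did not pass this test.

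Of 28 proliferation genes 15 were lower by this test (20 over the list alone, adjusted p = 3.23e-32, camera, and 0.00792 with an estimated correlation). Of 22 cholesterol synthesis genes 5 were higher (8 over the list alone, adjusted p = 1.29e-08, and adjusted p = 0.0629 with an estimated correlation), such as *Fdft1* at 1.22, and of 16 maturity markers 4 were lower (8 over the list alone, adjusted p = 3.44e-05, and adjusted p = 0.215 with an estimated correlation). The acinar list had a median of -3.63 beside these groups, with 0 of 20 called (adjusted p = 1.81e-08, and adjusted p = 0.555 with an estimated correlation). In all 345 genes differed, 169 higher and 176 lower, and 98 without the libraries above 20% acinar share. Without T1D 4 the count was 200, with only these groups fitted 132, among Qiagen libraries 24, with DESeq2 564 and with voom 710. The gene calls of the 2 models met in 39 genes higher in both (7.61 expected from the totals alone), 58 lower in both (10.9 expected), 0 higher in T1D and lower in T2D (6.63 expected) and 6 the other way (12.5 expected). Over all genes the 2 effects had a Pearson correlation of 0.156. The contrasts share no control animals.

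**Figure D4:**
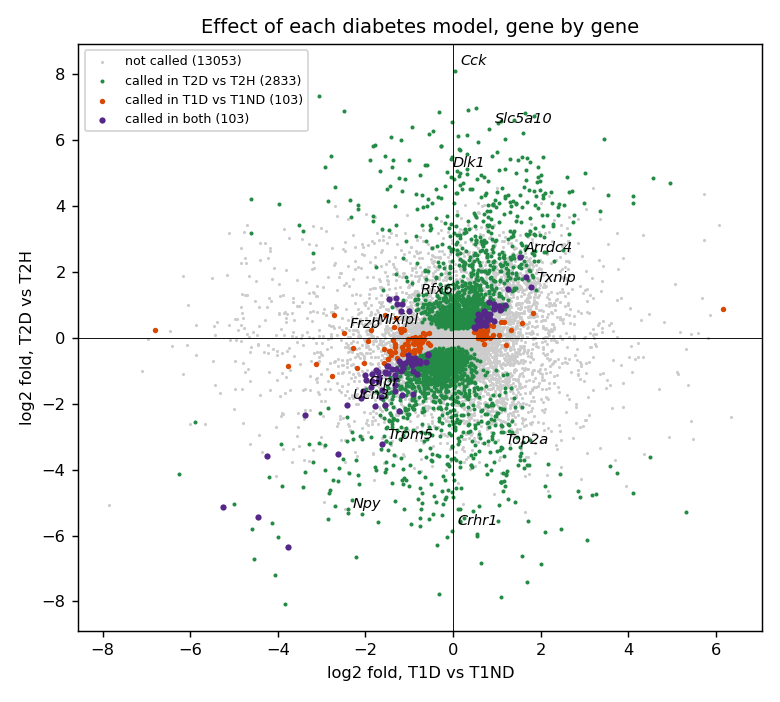
Log2 fold of each tested gene in T1D vs T1ND (x axis) and in T2D vs T2H (y axis), with 1 point per gene, coloured by the comparison in which it was called. The correlation over all genes is 0.156.

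**Figure D5:**
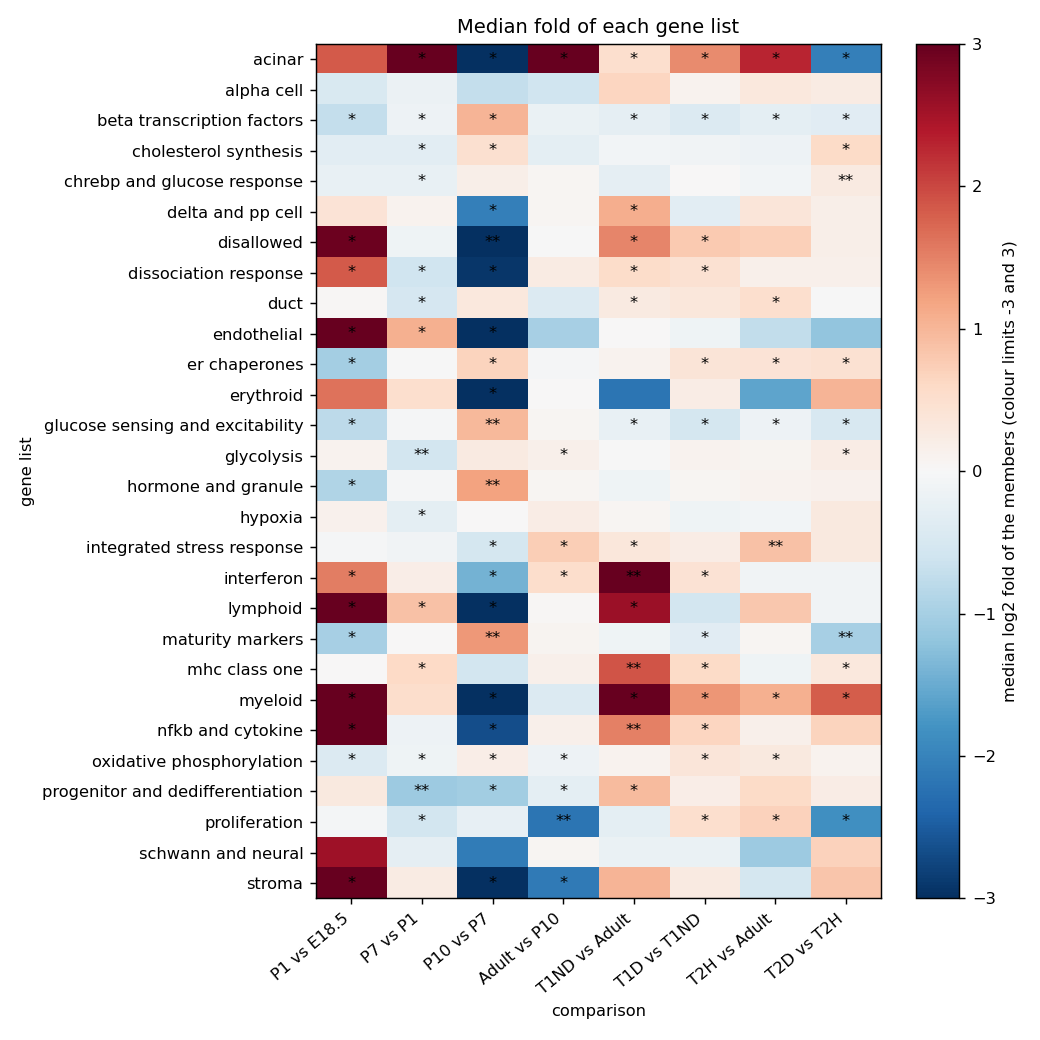
Median log2 fold of each gene list in 8 comparisons, colour limited to -3 and 3. One star marks an adjusted p below 0.05 (camera, preset correlation) and 2 stars one that also lies below 0.05 with an estimated correlation, as for the interferon list in T1ND (1.21e-05).

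The genes that stand out in the diabetes comparisons are protein-coding and lie, in GRCm38.p6, on chromosome 13 at 3940688 to 3945349 (*Ucn3*), chromosome 3 at 96557957 to 96561857 (*Txnip*) and 28697903 to 28728361 (*Slc2a2*), chromosome 2 at 80411970 to 80447396 (*Frzb*), chromosome 9 at 121489824 to 121495694 (*Cck*), chromosome 12 at 109452485 to 109463336 (*Dlk1*), chromosome 6 at 49822710 to 49829507 (*Npy*) and chromosome 11 at 61672782 to 61720817 (*Slc5a10*). The libraries carry no strand, so antisense reads at these places count with the gene.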

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

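The tests on P10 vs P7 below and the terms for marker lists of other cells were chosen after the results were seen. The value of a library was looked at closely where its gap to the nearest other library of its group passed Dixon's 95% limit, which happened in 19 of 90 looks, against about 1 in 20 groups by chance. The largest effects that differ between the diabetes models are listed with them.

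P10 vs P7. The change of 4731 genes went with stromal RNA in 2 of the 3 P7 libraries. Depth is argued against, since mean totals of P7 over P10 had a ratio of 0.958. With a stroma term the folds of the called genes were multiplied by a median of 0.662 (quartiles 0.507 to 0.804), the median size falling from 2.33 to 1.24 with errors 1.15 times as large, 4637 of 4731 keeping their direction and 263 still called. Without the libraries above 1% stroma 1 P7 library was left and 7 genes were called. RNA of stromal and other non-β cells and the age of the animals therefore cannot be told apart for these genes, because under 3 P7 libraries are low in stroma, and both stay open.

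T1D vs T1ND. The change of 206 genes went with a myeloid share of 0.554% in T1D and 0.242% in T1ND and with acinar shares of 23.3% and 14.8%. The duct share moved too (0.498 ± 0.124% in T1D and 0.232 ± 0.132% in T1ND), and no duct term was fitted. With an acinar term the folds had a median ratio of 0.998 (0.97 to 1.02) and 184 were still called, which argues against acinar RNA as the cause. With a myeloid term the median ratio was 0.862 (quartiles 0.796 to 0.952), so myeloid RNA is argued against as the whole cause. Still 12 of the 206 remained called, all 206 in the same direction. The median size was 0.83 against 1.03 and errors were 1.02 times as large, and why calls were lost was not tested. A part for myeloid cells in the islets stays open, as does the diabetes itself, which the design names and which was not tested apart.

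Proliferation genes in T2D vs T2H. The 22 called members had a median size of 2.63. With a term for log2 age their folds had a median ratio of 1.04 (1.01 to 1.06, 18 still called), with an acinar term 1.03 (1.00 to 1.07, 22 called) and among TRIzol libraries alone 1.09 (0.935 to 1.21, 15 called). Age, acinar RNA and the extraction method are thus argued against as causes. That ob/ob β cells of hyperglycaemic animals divide less than those of ob/+ animals remains as a hypothesis, found and tested on the same data. Counts of labelled dividing cells in ob/ob and ob/+ animals of the same strain, not used here, would test it. The strain background (BTBR/mix in T2D, BTBR in T2H) differs completely with diabetes and stays open as well, untested. The T2H animals reached 179 days and the T2D animals 78.

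Other splits of the same libraries were counted for each comparison, the real one among 22 that were drawn. No other split gave as many genes as the real one for Adult vs E18.5 (5594, highest other 2287), P1 vs E18.5 (1938, 956), P10 vs P7 (4731, 1671) and Adult vs P10 (3029, 11). The same held for T1ND vs Adult (2231, 28), T1D vs T1ND (206, 3), T2H vs Adult (836, 137), T2D vs T2H (2937, 813) and the difference of effects (345, 16). With 22 splits the smallest possible share is 1 in 22, and it was not adjusted over the 10 comparisons. Chance is therefore argued against in these comparisons but not excluded. For P7 vs P1 the 10 splits are too few to decide (17 genes, highest other 736, 3 splits with as many). What set apart the splits with 736 and 609 genes was not tested.

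Libraries that stood apart follow. Library 4 of E18.5 had an acinar share of 0.3173% (next 0.0984%). In T2H, library 1 had 65518931 counts (next 39606938) and a myeloid share of 0.1276% (next 0.0532%), library 2 had *Cartpt* at 3.719 CPM (next 0.9071) and *Cck* at 0.5404 (next 0.2532), library 6 had *Penk* at 109.3 (next 42.11), *Rasl11b* at 36.82 (next 16.89) and *Sorcs2* at 9.884 (next 1.254), and library 9, of the animal with the highest glucose of its group, had *Slc5a10* at 4.611 (next 2.272) and *Tm4sf20* at 1.618 (next 0.7951). The animal of T2H library 9 was also the oldest (179 days) and heaviest (60.4 g) of T2H, and its library the only Qiagen column one there. In T1ND, library 5, again of the animal with the highest glucose of its group and also the oldest (212 days) and heaviest (32.98 g), had *Txnip* at 313.1 CPM (next 89.74), *Arrdc4* at 59.94 (next 21.87) and *Gsto2* at 17.78 (next 8.805). T1ND library 1 had *Gipr* at 51.46 (next 19.58). Library 1 of T1D had a stromal share of 0.0154% (next 0.001%). In T2D, library 1 had 73839270 counts (next 44004925) and a mean distance of 0.4123 (next 0.2515), and library 3 an acinar share of 39.1311% (next 7.3486%) and *Slc39a8* at 3.101 CPM (next 1.39).

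T2D 1 and T2H 1, the deepest libraries of their groups, carry S numbers 17 and 18 in their labels. T2D 3 and T2D 4 carry these too, and no other S number is shared. What the S numbers stand for is not labelled. A run shared by T2D 1 and T2H 1 was not labelled and stays open. Without both, 2633 genes were called in T2D vs T2H (2937 with them), the score differed by -0.5381 (exact permutation p = 0.001998) and the spread by -0.01958 (exact permutation p = 0.6127).

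Effects that differed between the models by the test of the difference were those on *Cck* (8.057), *Sorcs2* (5.927), *Slc5a10* (5.515), *Dlk1* (5.172), *Crhr1* (-5.818), *Ube2c* (-4.773), *Top2a* (-4.461) and *Syt10* (-4.419). The effect on the spread within a group differed by 0.107 (permutation p = 0.00941, two-sided, 100000 permutations). It rests on 1 library, since without T2D replicate 1 it differed by 0.0381 (permutation p = 0.349). The permutations moved each library's distance without computing it anew, so the p values for the spread are approximate at best. The effect on the maturation score differed by 0.268 (permutation p = 0.482).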

How the results depend on the processing

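Terms or fits that handle RNA of other cells, the authors' factors, the score with or without genes of no adult counts, single libraries left out of shares and of the difference in spread, the settings for age of the score, and the fit without T2D 1 and T2H 1 were chosen after the data were seen; all other settings were fixed before. Of the recomputed comparison results 408 stayed within their limits, 87 counts moved by over 1.5 times, 6 results lost and 3 gained p below 0.05 and 3 turned. Of 8418 recomputed values of genes named in the report 7673 stayed called or stayed uncalled, 688 lost and 53 gained a call and 4 turned. A gene fold or set test counted as turned only where the main or the recomputed fit passed 0.05. Those that passed in neither stand among the kept ones, whatever their direction. The cause was not tested unless fewer libraries, fewer genes or a stricter limit made it. At least 2-fold, Adult vs E18.5 had 3147 of 5594 genes, Adult vs P10 1557 of 3029, T1ND vs Adult 1261 of 2231, T1D vs T1ND 107 of 206, T2H vs Adult 324 of 836 and T2D vs T2H 1406 of 2937. Among Qiagen libraries, which leave 1 library in E18.5, P1 and T2H, counts were 1861 (Adult vs E18.5), 0 (P1 vs E18.5, 1938 in the report), 6 (P7 vs P1, 17 in the report), 358 (P10 vs P7, 4731), 1003 (Adult vs P10), 0 (T1D vs T1ND), 17 (T2H vs Adult), 25 (T2D vs T2H) and 24 (difference of effects, 345). Among TRIzol libraries, which leave 1 library in P7, they were 3231, 9 (P7 vs P1), 1728 (P10 vs P7), 1195 (Adult vs P10) and 93 (T2H vs Adult). Without an extraction term P7 vs P1 had 11 and T1D vs T1ND 79. With only the groups compared, P7 vs P1 had 0, P10 vs P7 1656, T1D vs T1ND 0, T2D vs T2H 1293 and the difference 132. Unadjusted p lay below 0.05 for 4409 genes in P1 vs E18.5, 717 in P7 vs P1 and 2619 in T1D vs T1ND (edgeR, all libraries). Voom gave 6356 in P1 vs E18.5, 536 in P7 vs P1, 7803 in P10 vs P7, 4850 in Adult vs P10, 1821 in T1D vs T1ND and 710 in the difference. DESeq2 gave 50 in P7 vs P1, 576.0 in T1D vs T1ND (201 of the 206 among them), 1279 in T2H vs Adult and 564 in the difference. T2H vs Adult had 303 with sex, 319 with age and 1294 with 1 copy of Ins2-Cre, and T1D vs T1ND 124 with age. A stroma term gave 131 (P1 vs E18.5), 26 (P7 vs P1), 264 (P10 vs P7) and 366 (T1D vs T1ND), and a myeloid term 101 (P1 vs E18.5), 1202 (P10 vs P7), 776 (T1ND vs Adult) and 12 (T1D vs T1ND). Without the 4 libraries above 1% stroma counts were 26 (P1 vs E18.5), 3 (P7 vs P1), 7 (P10 vs P7) and 326 (T1D vs T1ND), and without those above 20% acinar 6 (T1D vs T1ND) and 98 (difference). With single libraries left out (replicate numbers), P1 vs E18.5 had 954 and 864 without E18.5 2 and 3, and 3281, 950 and 299 without P1 1, 2 and 3. P7 vs P1 had 7 and 10 without P1 2 and 3, and P10 vs P7 2779, 1585 and 6072 without P7 1, 2 and 3. T1D vs T1ND had 34, 65, 103, 684, 484 and 133 without T1ND 1, 2, 3, 5, 6 and 7, and 71, 35, 102 and 24 without T1D 1, 2, 3 and 4. T2H vs Adult had 551 without Adult 13 and 386 and 1187 without T2H 9 and 7, and the difference 200 without T1D 4 and 439 without T2D 7. A group left with 1 library is assumed to vary like the others. The T1D score with Adult vs P10 genes was -0.09525 (exact permutation p = 0.4788), and the T2D score -0.1867 with them (exact permutation p = 0.1584), -0.24 among Qiagen libraries, -1.102 among TRIzol libraries (exact permutation p = 0.00202), and -0.4619 without T2H animals above 84 days (exact permutation p = 0.08485). The values by extraction method have z from the ICR adults of that method alone, so their sizes are on other scales. With genes of no adult counts the scores differed by -0.751 in T1D and -0.4834 in T2D. The T2D difference in spread was 0.09547 without removal of the extraction effect (exact permutation p = 0.02526) and 0.1058 without T2H 9 (p = 0.00404), -0.009138 without T2D 1 (p = 0.8076), 0.09464 without T2D 6 (p = 0.02478) and -0.01958 without T2D 1 and T2H 1 (p = 0.6127). Lists called went, with an estimated correlation, from 12 to 2 (Adult vs E18.5), 14 to 0 (P1 vs E18.5), 14 to 2 (P7 vs P1), 20 to 4 (P10 vs P7), 8 to 1 (Adult vs P10), 14 to 3 (T1ND vs Adult), 13 to 0 (T1D vs T1ND), 9 to 1 (T2H vs Adult), 11 to 2 (T2D vs T2H) and 9 to 1 (difference). For T1D the rising set had camera p = 3.37e-05, and 0.867 in the opposite direction with Adult vs P10 sets, and the falling set p = 0.00119, 0.119 with an estimated correlation and 0.42 with Adult vs P10 sets. Folds of called genes that turned were *Cxcl1* (P1 vs E18.5, -0.167 without the 4 stroma libraries), *Col1a2* (P10 vs P7, 0.32 with a stroma term), and *Slc39a8* (0.877) and *Amy2a5* (5.118) in T2D vs T2H among Qiagen libraries. No paired analysis was possible because no label links animals of different groups. Within groups, the labels of P7 1 and P7 2 share an animal number up to a suffix, as do those of P10 2 and P10 3. The suffixes of P10 2 and P10 3 read like dates months apart, though no label says what they mean. Such dates would argue against a shared animal or litter for 10-day-old pups. Whether P7 1 and P7 2 share an animal or a litter is not labelled. Each library was counted on its own.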

Other observations

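The tests of sex, *Txnip* and relations within the ICR adults were added after the main results were seen. Further results on lists follow. Of 12 alpha cell genes 4 fell from E18.5 to Adult (6 over the list alone, adjusted p = 0.00911, camera, and adjusted p = 0.169 with an estimated correlation), such as *Slc38a5*, an amino acid carrier of alpha cells, at -6.00, and *Gcg*, glucagon, was not called there (1.06). Of 10 delta and PP cell genes 4 rose in T1ND vs Adult (5 over the list alone, adjusted p = 0.00478, and adjusted p = 0.237 with an estimated correlation), with *Sst*, somatostatin, at 1.75 and *Rbp4*, retinol-binding protein, at 2.35. Of 12 duct genes 4 rose in the same comparison (5 over the list alone, adjusted p = 0.0251, and adjusted p = 0.37 with an estimated correlation), such as *Spp1*, osteopontin, at 3.15. Of 13 endothelial genes 11 fell from P7 to P10 (12 over the list alone, adjusted p = 3.2e-06, and adjusted p = 0.18 with an estimated correlation), as did 7 of 7 erythroid genes (7 over the list alone, adjusted p = 0.0222, and adjusted p = 0.343 with an estimated correlation). Of 9 Schwann cell genes 3 fell there (3 over the list alone), and the list did not pass (adjusted p = 0.258). In T2D vs T2H the NF-kB and cytokine list had a median of 0.67 and the stromal list of 0.83, while camera placed both lower (adjusted p = 0.972 and 0.826).

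Male (n = 10) and female (n = 11) ICR adults were compared with extraction and age as terms. *Npy* was lower in males by 1.79 (188.6 ± 57.18 against 594.8 ± 166.9 CPM, adjusted p = 3.46e-05, edgeR), *Kdm6a*, an X-linked demethylase that escapes inactivation, by 1.26, and *Slc7a7*, an amino acid carrier, by 2.82. *Gria2*, a glutamate receptor subunit, was higher by 1.57 and *Ins2* by 0.78 (adjusted p = 0.0265, edgeR). These genes were chosen after their values were seen. Of 19 glycolysis genes 10 were lower in males (adjusted p = 1.52e-05, camera, and 0.0321 with an estimated correlation), and of 26 proliferation genes 8 were higher (adjusted p = 1.17e-05, and adjusted p = 0.573 with an estimated correlation). In all 1018 genes changed with sex, 518 higher and 500 lower in males (Y genes left out), and 833 among the Qiagen libraries (10 males and 7 females). All 4 TRIzol adults were female. Of 40 splits by sex only the real one gave as many genes (1018, highest other 127), which argues against chance without excluding it.

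The hypothesis that *Txnip* follows blood glucose within non-diabetic groups was tested in 3 groups with random or exact permutation tests, two-sided. Spearman's rho was -0.215 in ICR adults (permutation p = 0.346, adjusted 0.667, r = -0.222, permutation p = 0.335, adjusted 0.502, r = -0.144 without the 2 farthest animals, n = 21), 0.357 in T1ND (exact permutation p = 0.444, adjusted 0.667, r = 0.817, permutation p = 0.0984, adjusted 0.295, r = 0.023 without the 2 farthest, n = 7) and -0.1 in T2H (permutation p = 0.81, adjusted 0.81, r = 0.152, permutation p = 0.689, adjusted 0.689, r = -0.139 without the 2 farthest, n = 9). The test in T1ND was chosen after an outlying *Txnip* value there was seen. Nothing is decided in any group, since the 95% intervals of rho (Fisher's z) reached from -0.595 to 0.244, from -0.563 to 0.882 and from -0.718 to 0.606.

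Within the ICR adults (n = 21) 3 relations were tested by permutation, two-sided, adjusted over the 3. They were chosen after the scores, ages, glucose values and shares of each library were seen, before any correlation was computed. The maturation score rose with age by rank (rho = 0.538, permutation p = 0.0128, adjusted 0.0385), while r was 0.31 (permutation p = 0.171, adjusted 0.171, r = 0.42 without the 2 farthest animals). Over the 48 libraries of the adult groups, with the groups as terms, the slope per doubling of age was 0.0628 ± 0.089 (p = 0.483, linear model). The relation of the score to glucose was not decided (rho = -0.357, permutation p = 0.111, adjusted 0.111, and r = -0.332, permutation p = 0.143, adjusted 0.171, r = -0.298 without the 2 farthest). The insulin share against the acinar share gave rho = -0.438 (permutation p = 0.0485, adjusted 0.0727) and r = -0.54 (permutation p = 0.0113, adjusted 0.034, r = -0.379 without the 2 farthest). Both are shares of the same library total, so a negative relation is partly built in. The tests therefore cannot tell how far acinar RNA dilutes the insulin share. Among 17 Qiagen adults the 3 values of rho were 0.588, -0.314 and -0.566.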
